A study of Homo sapiens with 6 samples.

How the data were processed

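RNA was extracted from Kasumi-1 cells with a non-targeting guide (3 libraries) and with a SETD8 knockout (3 libraries). Per the labels' protocols, polyadenylated RNA was selected with poly-T beads and libraries were made with a directional NEBNext kit, which marks strand. Whether the counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain. Per the submitters' processing notes, the build was hg38 and the tools included HISAT2, an aligner, and DESeq2, a count model. Versions, the gene counter and its settings are not given in the sources used here.

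The deposited table holds, per the file headers, 1 column of normalized read counts for each library, gene coordinates, biotype and the authors' own comparison. The values per library are a signal that is never negative: the authors' read counts divided by a size factor for each library. Dividing each deposited value by what 1 read is worth in its library gave whole numbers, within 0.001, for 100% of the values in each library, with size factors from 0.959 to 1.07. For control 3 and SETD8 knockout 2, where 1 read is worth 0.991 and 0.993, a step this near 1 cannot be told from rounding by code, so whole reads there are less certain, as are the count tests that use them. The authors deposited a log2 fold change for each gene. The authors also deposited a p-value and an adjusted p-value for each gene, and the largest deposited p-value was 0.049998. The ratio of adjusted to unadjusted p-values shows an adjustment over 19860 genes, of which the listed genes with an adjusted p below 1 are 40.1%. The other 23 of the 7983 listed genes had an adjusted p given as 1. All tests here therefore ran on genes already selected for a difference between these groups, and the spread that limma pools over genes comes from selected genes. The table's coordinates were compared with GENCODE release 29 on the same build: 7974 of 7983 genes had the same chromosome, start and end.

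Genes with a mean of at least 10 over the 6 libraries were tested, 7516 in all, which left out 467. The test planned for normalized counts was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), two-sided, with no block. Benjamini-Hochberg adjustment assumed 19860 genes, as the authors' adjustment did, and a gene was called at adjusted p below 0.05. Before the data were examined, 37 gene lists and the rule for named genes were fixed. Lists with at least 5 tested members, 33 in all, were tested with camera at a preset inter-gene correlation of 0.01 against the other listed genes, with Benjamini-Hochberg adjustment over the lists. Counts of members use the adjusted p over all genes, and counts adjusted over the list alone are given beside them. They cover tested members only, so genes of a list outside the table are not counted. Most tested genes were called, so the share of a list's members that was called says little, and the direction says more. Named genes were KMT5A, then the 10 higher and the 10 lower protein-coding genes with the largest change among those with a mean of at least 100 and no overlap between groups. For each list the rule took up to 4 called members with the largest change and a mean of at least 50, or the member with the highest mean where none was called. Chance alone leaves a gene without overlap in 10% of cases with 3 libraries against 3.

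On simulated counts for the 7516 genes of this comparison, with 200 changed genes, the limma test recovered 52% of genes changed 1.25-fold, 88% at 1.5-fold, 84% at 2-fold and 96% at 4-fold, with 7 false calls and 0 wrong signs. The camera test found a planted list of 60 genes with a p of 1.08e-34, and 7 of 200 unchanged lists had a p below 0.05. Simulated genes were drawn independently, so these lists cannot show whether the preset correlation of 0.01 holds for the real data. There the estimated correlations of the lists ran from -0.12 for megakaryocyte genes to 0.94 for subunits encoded by mitochondrial DNA. Depth was 10966349 to 12557974 reads in listed genes, and total library depth is not given in the sources used here. Libraries of a group differed by more than counting noise, with chi-square per degree of freedom from 3.87 to 12.2, so no library was treated as a repeat of another.

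Alternatives fixed before the data were examined were TMM and upper-quartile scaling, DESeq2 1.42.0 and edgeR 4.0.16 quasi-likelihood tests on the recovered reads, other filters and pseudocounts of 0.5 and 5. Further ones were a replicate block, leaving out each library, a log2 fold change of at least 1, camera with estimated correlation, fry, and protein-coding genes only. Those added after the values were seen were adjustment over the table's genes only, Fisher's exact test of direction within lists, and 3 removals of a trend from the knockout libraries. The first trend was a local regression (span 0.5) of log2 fold change on gene length and on the GC content of the longest GENCODE transcript, which 7982 of 7983 genes had. The second was the median log2 fold change of the 20 nearest other tested genes on the chromosome, and the third joined both. Genes with little change are mostly outside the table, so this median can lie away from 0 even where directions are mixed. Genes of mitochondrial DNA had no such trend taken from them. Segments were 10 Mb long and held at least 20 genes with a mean of at least 50. Figures were drawn with matplotlib 3.10.9.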

Results

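RNA sequencing was performed on Kasumi-1 cells, a human acute myeloid leukaemia cell line that carries the t(8;21) translocation joining RUNX1 to RUNX1T1. Cells with a CRISPR/Cas9 knockout of SETD8, the histone H4 lysine methyltransferase whose current symbol is KMT5A, were compared with cells that carried a non-targeting guide (sgNT, called control here). Each group had 3 libraries. The deposited table held 7983 genes, each of which had an unadjusted p of at most 0.049998 in the authors' deposited table, so a gene outside it was not analysed here and cannot be called unchanged. Reads in the listed genes ranged from 10966349 in control 1 to 12557974 in SETD8 knockout 3. The labels do not say whether the numbered libraries were separate cultures or separate guides, so p-values measure the spread between these samples, which may be technical. Values below are normalized read counts, as mean ± SD with n = 3 per group, and log2 fold changes are knockout over control on the log2(value + 1) scale, which understates the change of low genes.

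The targeted gene was lower in all 3 knockout libraries. KMT5A (ENSG00000183955, chromosome 12, 123383773 to 123409358, hg38) read 1191, 1212 and 1255 in the control libraries and 880, 933 and 939 in the knockout libraries. Its log2 fold change was -0.41 (SE 0.07, limma-trend adjusted p = 5.65e-05), a 1.33-fold lower level. Most of the transcript signal therefore persisted, and a CRISPR indel need not lower the mRNA of the gene it disrupts. Among 4 tested genes of the list on H4 lysine methylation, 1 was higher and 3 were lower, with the same counts when adjusted over the list alone; the median log2 fold change was -0.38 and the mean 0.38. The higher gene was L3MBTL3, a reader of methylated lysines, at 25.9 ± 15.9 in control and 163 ± 14.6 in knockout. DTL, part of the ubiquitin ligase that degrades SETD8 protein in S phase, and ORC1, a subunit of the origin recognition complex, were lower, with log2 fold changes of -0.51 and -0.34.

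Most of the listed genes passed the test here, in both directions, which their selection by the authors' test of the same 6 libraries made near certain. Of 7516 tested genes, 3557 were higher and 3513 were lower at adjusted p below 0.05 (limma-trend, Benjamini-Hochberg over 19860 genes). The 7070 called genes stand against the 19860 genes adjusted over, most of which are outside the table. With a log2 fold change of at least 1 in size, 627 were higher and 804 were lower. The authors' deposited table gave 3350 higher and 3311 lower genes at the same threshold.

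The genes named in this paragraph are the 10 higher and 10 lower with the largest change among protein-coding genes with a mean of at least 100 and no overlap between groups. Among those that rose, HGF, which encodes hepatocyte growth factor, went from 102 ± 5.84 to 26171 ± 453 (chromosome 7, 81699008 to 81770438), a log2 fold change of 8.00 (SE 0.06, adjusted p = 2.94e-28). ADAMTS9, a secreted metalloprotease, rose from 5.88 ± 5.17 to 419 ± 17.1, and FCGBP, which encodes an IgG Fc binding protein, from 7.28 ± 1.41 to 526 ± 104. PRTN3, which encodes the neutrophil granule protease proteinase 3, rose from 58.2 ± 8.27 to 1754 ± 53.4 (log2 fold change 4.90, adjusted p = 2.86e-18). EMC10, OCIAD2, HSBP1L1, SPINT1, SYT1 and RBMS1 completed the 10 higher genes, with log2 fold changes of 5.37, 4.50, 4.26, 4.03, 3.93 and 3.59. Among those that fell, the change was largest for FLRT2, which encodes a membrane protein of neuronal guidance and cell adhesion and went from 296 ± 40.1 to 0.662 ± 1.15. It had 895 reads over the control libraries and 2 over the knockout libraries, a ratio of 451 with an exact 95% binomial interval of 124 to 3727 that covers counting error only. ZNF618, NEGR1, SIGLEC6, SIPA1L2, KLHL13, LY86, MFAP4, INHBA and PADI3 followed within this set, with log2 fold changes of -5.94, -5.87, -5.23, -5.19, -4.86, -4.70, -4.49, -4.25 and -4.12. INHBA encodes the activin A subunit and fell from 442 ± 33.5 to 22.6 ± 5.11, and SIGLEC6, a sialic acid binding receptor, fell from 391 ± 22.2 to 10.1 ± 4.24. Adjusted p was at most 1.79e-09 for all 20 of these genes.

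**Figure D1:**
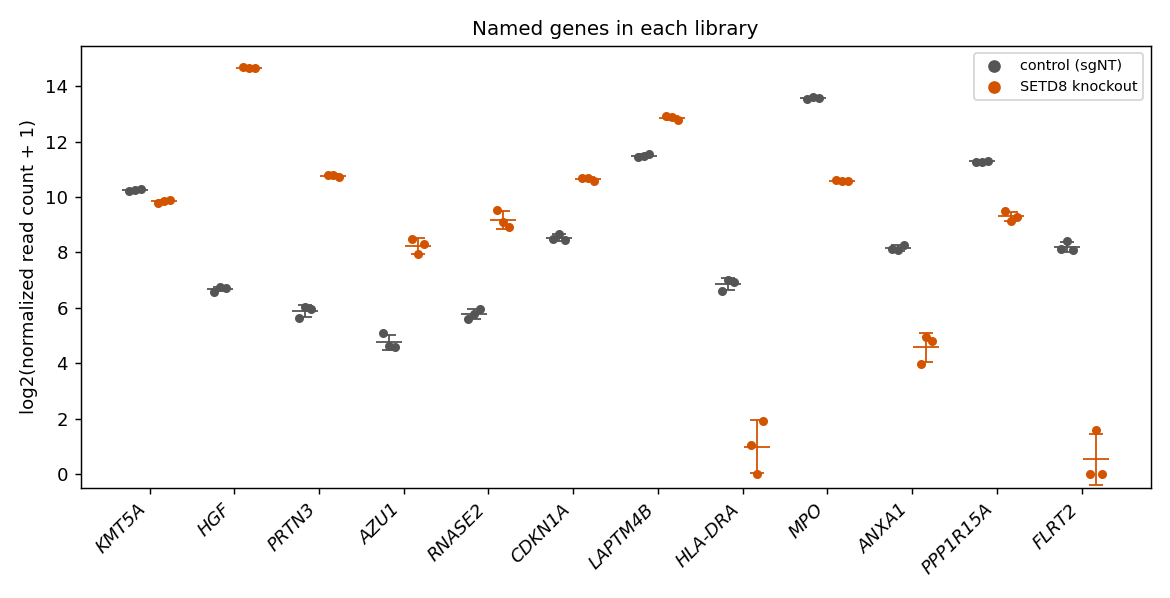
Normalized read counts of 12 named genes in each library, as log2(value + 1). Points are libraries, bars are the mean and SD of 3 libraries, grey for control and orange for SETD8 knockout; HGF moves from a control mean of 102 to 26171, and FLRT2 from 296 to 0.662.

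The direction of change was grouped along the chromosomes, a feature found after the values were seen. Here and for gene length, higher means a log2 fold change above 0, whether or not the gene passed the test. Among genes with a mean of at least 50, 21.8% of 303 genes on chromosome 9, 24.5% of 494 on chromosome 17 and 26.8% of 209 on chromosome 20 were higher in knockout cells. On chromosome 21, 64 of 74 genes were higher, as were 73.5% of 245 genes on chromosome 8. In segments of 10 Mb, 0 of 30 genes were higher between 10 and 20 Mb of chromosome 16, and 1 of 34 between 110 and 120 Mb of chromosome 10. Between 120 and 130 Mb of chromosome 9, 3 of 70 genes were higher, and between 60 and 70 Mb of chromosome 17, 2 of 47. Between 0 and 10 Mb of chromosome 5, 20 of 22 genes were higher, with a median log2 fold change of 0.65. Direction also followed gene length: 67.5% of the 679 shortest genes, up to 2152 bases, were higher, with a median log2 fold change of 0.40, against 36.1% of the 678 longest, from 10891 bases, with a median of -0.29.

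**Figure D2:**
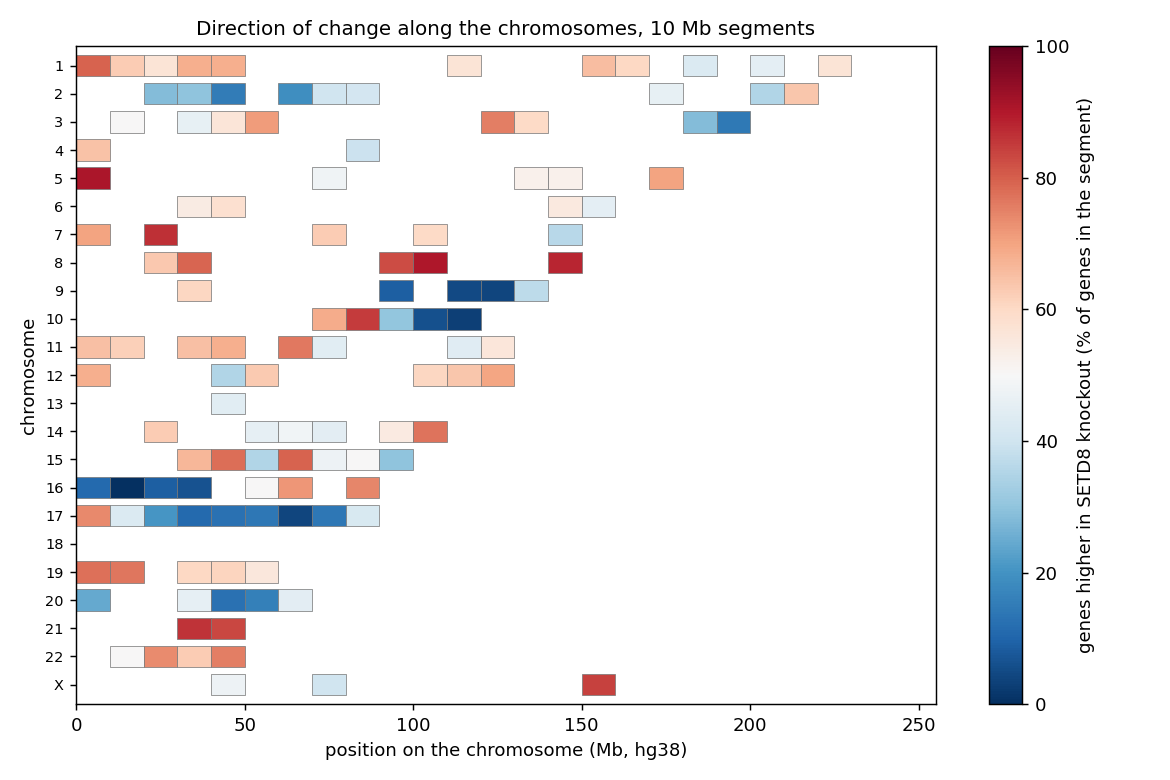
Share of genes with a log2 fold change above 0 in SETD8 knockout cells in each 10 Mb segment of the genome that held at least 20 genes with a mean of at least 50, by chromosome (vertical axis) and position in Mb (horizontal axis). Red segments hold mostly higher genes and blue segments mostly lower genes; 20 of 122 segments held at most 20% higher genes outside the gene lists, among them 4 neighbouring segments of chromosome 16 and 5 of chromosome 17.

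The series title raises mitochondrial homeostasis as a question, and nuclear genes of the respiratory chain rose together in knockout cells. Of 37 subunit genes written in the complex I list, 23 were tested, in a table selected for change. Of these, 22 were higher and 0 were lower, with a median log2 fold change of 0.68 (camera adjusted p = 2.25e-05, 0.54 with an estimated correlation). NDUFC2 rose from 194 ± 40.2 to 413 ± 12.9, NDUFS6 from 1392 ± 191 to 2968 ± 413 and NDUFB2 from 644 ± 68.8 to 1341 ± 107. In complexes II to V, 35 of 37 were higher, with a median of 0.50 (camera adjusted p = 2.17e-05, 0.54 with an estimated correlation). ATP5PF, a subunit of ATP synthase, rose from 834 ± 80.1 to 1667 ± 294, and COX6C of cytochrome oxidase from 2078 ± 66.2 to 4001 ± 228. The 2 lower members, UQCRC2 on chromosome 16 and ATP5PD on chromosome 17, were singled out after their values were seen, with log2 fold changes of -0.45 and -0.37. Adjusted over the list alone, the counts were 23 higher and 0 lower in complex I and 35 higher and 2 lower in complexes II to V. The 60 nuclear subunit genes had a median length of 2469 bases against 5086 bases for all tested genes, and with both the length and GC trend and the trend of neighbouring genes removed the complex I call ended (median 0.19, adjusted p = 0.085). NDUFS6 and ATP5PF lost their calls there too, at log2 0.046 (adjusted p = 1) and 0.23 (0.12).

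Of 13 genes written in the list of subunits encoded by mitochondrial DNA, 8 were in the table, which was selected for change. All 8 rose, also when adjusted over the list alone, with a median log2 fold change of 0.46 (camera adjusted p = 0.037, 0.58 with an estimated correlation). MT-CYB, the cytochrome b of complex III, rose from 16416 ± 793 to 34885 ± 5389, and MT-ND1 of complex I from 20596 ± 1455 to 29702 ± 5459. MT-ND1 lost its call with both trends removed (log2 0.24, adjusted p = 0.052). All genes of mitochondrial DNA in the table took 4.62%, 4.63% and 4.95% of the listed reads in the control libraries and 5.86%, 4.88% and 4.88% in the knockout libraries, so the 2 groups overlapped in that share. The list's call ended at a similar median without control 1 (0.42, adjusted p = 0.065), without control 2 (0.41, 0.072) and with a DESeq2 Wald test as the basis of the list test (0.47, 0.13). It ended at a median of 0.22 with the length and GC trend removed (adjusted p = 0.24) and with both trends removed (0.18). No trend of neighbouring genes was taken from mitochondrial DNA, so these 2 settings gave its genes the same log2 fold changes.

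Genes of the mitochondrial ribosome and of the tricarboxylic acid (TCA) cycle moved in the same direction. Of 74 mitochondrial ribosomal protein genes written in the list, 49 were tested. Among these, 42 were higher and 5 were lower (43 and 6 adjusted over the list alone), with a median of 0.37 (camera adjusted p = 0.0015, 0.55 with an estimated correlation). MRPL13 rose from 689 ± 41.2 to 1297 ± 155, while MRPL10, on chromosome 17, fell from 1537 ± 142 to 848 ± 49.9. The list lost its call with the length and GC trend removed (median 0.20, adjusted p = 0.092), with the trend of neighbouring genes removed (0.098, adjusted p = 0.060) and with both removed (0.092, adjusted p = 0.39). MRPL10 lost its own with the trend of neighbouring genes removed (-0.18, adjusted p = 0.094). In the TCA cycle, 13 of 16 genes were higher and 2 were lower (14 and 2 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.023, 0.55 with an estimated correlation, 0.057 with the edgeR test and 0.0575 with the DESeq2 test as its basis). SDHA, shared by the TCA cycle and complex II, rose from 3981 ± 308 to 6466 ± 280, and PC, pyruvate carboxylase, from 287 ± 29.4 to 435 ± 20.9. SDHA lies in the segment at the start of chromosome 5 where 20 of 22 genes were higher. With the trend of neighbouring genes removed, SDHA was at log2 0.049 (adjusted p = 1) and PC at 0.31 (0.064), and with both trends removed the TCA list had a median of 0.35, no smaller than before, and an adjusted p of 0.0503.

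Other mitochondrial lists did not pass the planned list test. In fatty acid oxidation 10 of 12 genes were higher and 2 were lower, with a median of 0.43 (adjusted p = 0.065). The list passed with the trend of neighbouring genes removed (adjusted p = 0.045) and with both trends removed (0.025). DECR1, a reductase of unsaturated fatty acid oxidation, rose 1.75-fold and CPT2, carnitine palmitoyltransferase, 1.73-fold. In mitochondrial biogenesis and mtDNA maintenance, 8 of 14 genes were higher and 3 were lower (adjusted p = 0.25). TFB2M, a mitochondrial transcription factor, rose from 323 ± 46.6 to 611 ± 73.9, and MGME1, a mitochondrial exonuclease, fell from 704 ± 11.3 to 406 ± 17.5, a call that ended with the trend of neighbouring genes removed (log2 -0.21, adjusted p = 0.072). The mitochondrial unfolded protein response had 9 higher and 3 lower genes (adjusted p = 0.25), with ATF5, its transcription factor, falling 2.32-fold while the chaperonin HSPE1 rose 2.27-fold. Mitochondrial dynamics and mitophagy had 5 higher and 4 lower genes of 11 (adjusted p = 0.85), with the mitophagy receptor OPTN rising from a mean of 21.5 to 172 and CALCOCO2, another receptor, falling from 3397 ± 54.0 to 1758 ± 77.5. With both trends removed CALCOCO2 was at log2 -0.097 (adjusted p = 0.34) in place of -0.95. Adjusted over the list alone, these 4 lists had 10, 10, 9 and 6 higher and 2, 4, 3 and 5 lower genes.

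Genes of the integrated stress response, the ATF4 programme, fell. Of 21 tested genes 19 were lower and 1 was higher (20 and 1 adjusted over the list alone), with a median log2 fold change of -0.65 (camera adjusted p = 2.25e-05, 0.54 with an estimated correlation). PPP1R15A, which encodes the phosphatase subunit GADD34, fell from 2495 ± 35.9 to 632 ± 77.2, and DDIT4, an inhibitor of mTORC1, from 8453 ± 275 to 3208 ± 142. CTH, an enzyme of cysteine synthesis, fell 2.57-fold, and DDIT3, the transcription factor CHOP, 2.44-fold. The higher gene was STC2, singled out after its value was seen, with a log2 fold change of 0.51.

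Antioxidant genes rose, with 11 of 14 higher and 2 lower (12 and 2 adjusted over the list alone) and a median of 0.47 (camera adjusted p = 0.013, 0.55 with an estimated correlation). PRDX1, a peroxiredoxin, rose from 1703 ± 87.7 to 3966 ± 303, SOD1, the cytosolic superoxide dismutase, from 2712 ± 28.7 to 5901 ± 483, and CAT, catalase, from 3512 ± 142 to 5731 ± 381. This call ended with the length and GC trend removed (median 0.37, adjusted p = 0.14), with the trend of neighbouring genes removed (0.37, 0.058) and with both removed (0.20, 0.39). Of 23 genes in the MYC target list, most of them ribosome biogenesis factors, 17 were higher and 2 were lower (19 and 4 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0042, 0.54 with an estimated correlation). HSPE1 led this list, followed by NOP16, which rose from 390 ± 15.7 to 848 ± 2.37. MYC itself, singled out after its value was seen, had a log2 fold change of -0.13 and did not pass the test.

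Mitotic genes rose. The G2 and mitosis list had 42 written genes, of which 25 were tested. Of these, 20 were higher and 4 were lower (21 and 4 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.013, 0.54 with an estimated correlation). CCNB1, cyclin B1, rose from 1301 ± 25.3 to 2696 ± 154, the kinesin KIF20A from 657 ± 44.5 to 1330 ± 55.5 and PTTG1, securin, from 551 ± 7.29 to 1108 ± 88.6. The 4 lower members, seen after the fact, were MKI67 and BUB3 on chromosome 10 and CDC25B and UBE2C on chromosome 20. DNA replication genes went both ways, with 11 higher and 13 lower of 26 (12 and 14 adjusted over the list alone; camera adjusted p = 0.76). CCNE2 and CCNE1, the E-type cyclins, rose 1.97-fold and 1.62-fold, while TK1, thymidine kinase, fell from 5170 ± 76.7 to 3563 ± 103. Among 19 DNA damage repair genes 8 were higher and 11 were lower, also when adjusted over the list alone (adjusted p = 0.61). BRIP1, a helicase on chromosome 17, fell from 1612 ± 66.2 to 847 ± 46.4, and the checkpoint kinase CHEK2 rose 1.55-fold. With both trends removed BRIP1 was at log2 -0.12 (adjusted p = 0.29) and CCNE1 at 0.18 (0.42), and neither kept its call. Of 38 replication-dependent histone genes written in the list, 4 were in the table and 3 were tested, too few to speak for the list. Of these, 2 were higher and 0 lower (3 and 0 adjusted over the list alone). The higher genes, named after their values were seen, had low counts in this poly-T-selected RNA. HIST1H2BH went from a control mean of 12.3 to 68.0 in knockout, and HIST1H2AG from 6.95 to 20.8. HIST1H2BK, at 49.2 ± 8.42 and 75.5 ± 9.49, had an adjusted p of 0.052. It passed with no filter on low values (0.0497), with a pseudocount of 5 (0.042) and without control 1 (0.036). With the trend of neighbouring genes removed HIST1H2BK was at log2 1.03 (adjusted p = 0.0011) in place of 0.61.

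Targets of p53 did not move as a group, with 6 higher and 7 lower of 14 (7 and 7 adjusted over the list alone; adjusted p = 0.78). CDKN1A, which encodes the cell cycle inhibitor p21, rose from 371 ± 33.8 to 1615 ± 70.6. BBC3, the apoptosis inducer PUMA, fell from 475 ± 5.71 to 150.4 ± 34.1, and GADD45A fell 2.14-fold. Of 11 BCL2 family genes 4 were higher and 7 were lower, also when adjusted over the list alone (adjusted p = 0.28). After BBC3, BCL2A1 fell from a mean of 187 to 69.8, BCL2 from 6647 ± 222 to 3584 ± 184, and the pro-apoptotic BID rose 1.75-fold.

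Metabolic lists outside the mitochondrion leaned lower without passing the list test. In glycolysis 10 of 16 genes were lower and 4 were higher (10 and 5 adjusted over the list alone; adjusted p = 0.17, 0.037 with DESeq2 as the basis). ENO2, an enolase, fell from 877 ± 49.4 to 348 ± 16.7, HK2, hexokinase 2, from 22315 ± 868 to 9591 ± 360 and the glucose transporter SLC2A3 from 5398 ± 53.7 to 2463 ± 59.1. In cholesterol synthesis 11 of 15 genes were lower and 3 were higher (11 and 4 adjusted over the list alone; adjusted p = 0.061). HMGCS1, the synthase upstream of HMG-CoA reductase, fell from 6822 ± 407 to 2775 ± 100.0, and STARD4, a sterol carrier, from 3671 ± 141 to 1569 ± 105. The cholesterol list passed with DESeq2 (adjusted p = 0.019), edgeR (0.025), the replicate block (0.0496) and without control 3 (0.046). It also passed with the trend of neighbouring genes removed (median -0.62, adjusted p = 0.0053) and with both trends removed (-0.66, 0.010), against a median of -0.37 before.

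**Figure D3:**
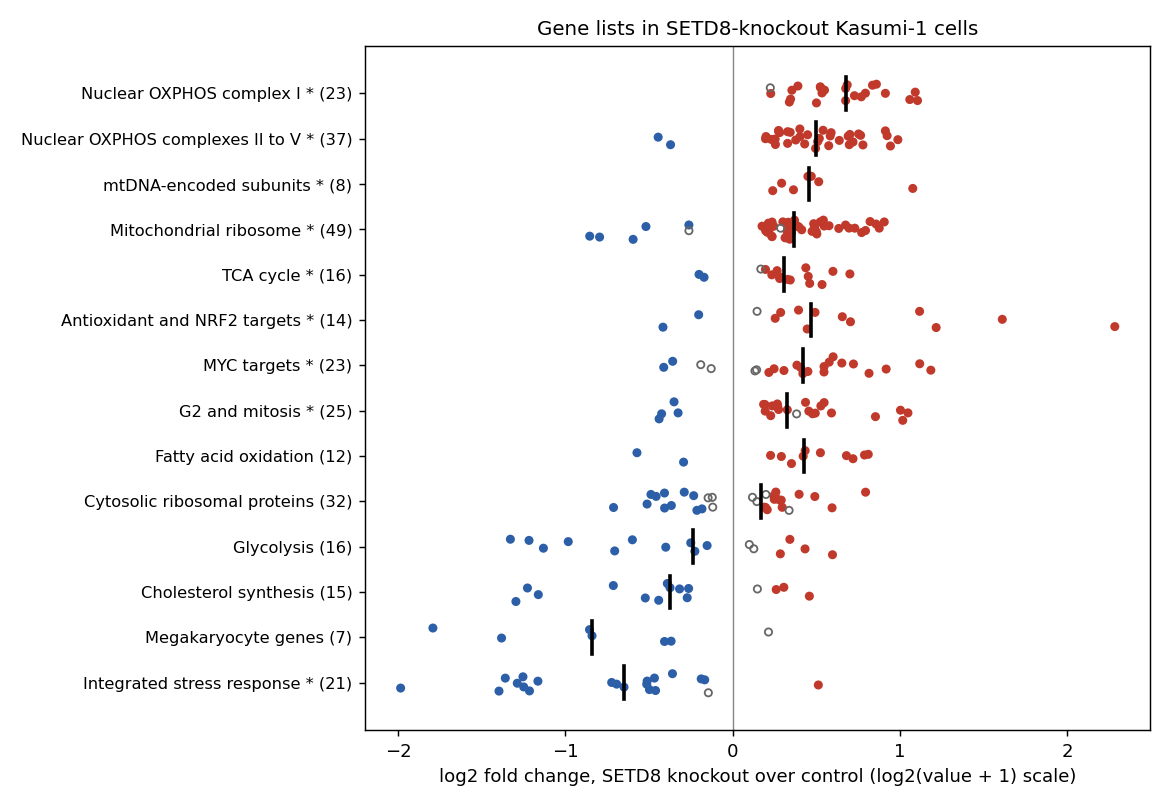
Log2 fold change of each tested member of 14 gene lists, knockout over control. Each point is a gene, filled at adjusted p below 0.05 (red higher, blue lower) and open otherwise, the black bar is the list median, the number of tested genes is in parentheses, and an asterisk marks the 9 lists past the list test; complex I has a median of 0.68 and the integrated stress response a median of -0.65.

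The title also names leukaemia stem cells. Of 9 tested genes of the 17-gene leukemic stem cell score 3 were higher and 5 were lower (4 and 5 adjusted over the list alone; adjusted p = 0.73). LAPTM4B, a lysosomal membrane protein, rose from 2869 ± 111 to 7471 ± 362, ARHGAP22 fell 2.14-fold and SMIM24 from 730 ± 79.2 to 347 ± 24.0. CD34, the stem and progenitor surface antigen, was singled out after its value was seen: its log2 fold change was 0.13 with an adjusted p of 0.070. Of 12 stem and progenitor transcription factors 7 were higher and 4 were lower (8 and 4 adjusted over the list alone; adjusted p = 0.45). HOXA10 rose from 75.2 ± 11.5 to 158 ± 35.2, TAL1 from 476 ± 15.6 to 822 ± 32.8, CEBPA from 169 ± 50.9 to 258 ± 10.6 and RUNX1 from 4262 ± 82.8 to 6691 ± 524. With the trend of neighbouring genes removed, HOXA10 (log2 0.52, adjusted p = 0.091), CEBPA (0.33, 0.28) and RUNX1 (0.11, 0.31) lost their calls, and CEBPA also lost it with the length and GC trend removed (0.34, 0.20). RUNX1 lies on chromosome 21, where 64 of 74 genes were higher, and counts of the gene do not separate the normal transcript from the fusion. Of 8 t(8;21)-associated genes 4 were higher and 3 were lower (5 and 3 adjusted over the list alone; adjusted p = 0.76), with a median of 0.26 and a mean of -0.56. The median turned to -0.34 with the trend of neighbouring genes removed and to -0.24 with both trends removed. The neural transcription factor POU4F1 rose 1.43-fold.

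Genes of myeloid maturation changed by large amounts in both directions. Of 15 tested granulocytic genes, from 33 written, 11 were higher and 4 were lower, also when adjusted over the list alone (adjusted p = 0.15). Beside PRTN3, the neighbouring granule gene AZU1 on chromosome 19 rose from 26.3 ± 5.57 to 305 ± 56.6, while ANXA1, annexin A1, fell from 287 ± 20.8 to 23.8 ± 8.11. MPO, the myeloperoxidase of primary granules, fell from 12254.5 ± 373 to 1541 ± 27.3, a log2 fold change of -2.99. Of 9 tested monocyte and macrophage genes, from 30 written, 6 were higher and 3 were lower, also when adjusted over the list alone (adjusted p = 0.35). TLR2, a receptor for bacterial lipoproteins, rose from 157 ± 50.1 to 763 ± 53.8. Of 7 megakaryocyte genes 6 were lower and 0 higher (6 and 1 adjusted over the list alone; adjusted p = 0.074), led by RAB27B, from 605 ± 51.1 to 174 ± 5.74. In the mast cell, basophil and eosinophil list 2 of 5 genes were higher and 3 were lower, also when adjusted over the list alone (adjusted p = 0.95), with a median of -0.48, a mean of 0.62 and a list test that pointed higher. RNASE2, an eosinophil granule ribonuclease, rose from 53.6 ± 6.72 to 587 ± 132, and KIT, the stem cell factor receptor, fell from 60704 ± 955 to 43551 ± 793. The 4 erythroid genes split evenly, with 2 higher and 2 lower, also when adjusted over the list alone, and CA2, carbonic anhydrase 2, fell 2.84-fold. Among lymphoid lists, 6 of 7 B cell genes were higher and 1 was lower (adjusted p = 0.14), with CD79B of the B cell receptor rising from 73.0 ± 23.6 to 524 ± 23.5. Of 4 T and NK cell genes 3 were higher and 1 was lower, with IL7R rising 2.34-fold, and both lymphoid lists had the same counts when adjusted over the list alone.

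Antigen presentation genes divided between higher and lower members. Of 13 genes 9 were higher and 3 were lower (9 and 4 adjusted over the list alone; adjusted p = 0.094), with a median of 0.60 and a mean of -0.10. HLA-DRA, the class II alpha chain, fell from 115 ± 16.7 to 1.28 ± 1.42, with 347 reads over the control libraries and 4 over the knockout libraries. CIITA, the class II transactivator, fell from 290 ± 4.29 to 80.2 ± 5.72. CD74, the class II invariant chain, rose from 543 ± 16.4 to 1270 ± 128. HLA genes share sequence, so their counts are uncertain. The list passed with DESeq2 (adjusted p = 0.028) and edgeR (0.044) as the basis.

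Inflammatory and stress lists did not pass. Of 12 NF-kB and inflammatory genes 8 were lower and 4 were higher, also when adjusted over the list alone (adjusted p = 0.17): TRAF1 fell from 859 ± 67.6 to 151 ± 16.8 and the chemokine CXCL8 from 2475 ± 202 to 584 ± 75.5. Of 19 interferon response genes 11 were higher and 5 were lower (12 and 7 adjusted over the list alone; adjusted p = 0.20), led by the RNA sensor DDX58, which rose 2.17-fold. The ER stress list had 7 higher and 6 lower genes, also when adjusted over the list alone (adjusted p = 0.61), and HSP90B1, an ER chaperone, rose from 10120 ± 268 to 17602 ± 602. In the heat shock list 10 of 14 genes were higher and 4 were lower, also when adjusted over the list alone (adjusted p = 0.25), with a median of 0.36 and a mean of -0.04. HSPA1B and HSPA1A, near-identical copies whose counts are uncertain, fell 5.79-fold and 3.54-fold. Of 32 cytosolic ribosomal protein genes 14 were higher and 11 were lower (17 and 11 adjusted over the list alone; adjusted p = 0.81). RPL12 on chromosome 9 fell 1.64-fold, to log2 -0.077 (adjusted p = 0.84) with the trend of neighbouring genes removed, and ribosomal protein counts are uncertain where processed pseudogenes share their reads.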

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

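The trend removals, the adjustment over the table's genes and Fisher's test of direction were chosen after the values were seen. KMT5A was lower under every alternative run, with log2 fold changes from -0.38 to -0.45 outside the trend removals and -0.42 to -0.76 within them. Scaling, filters, pseudocounts, the DESeq2 and edgeR tests and the authors' table gave 3229 to 3725 higher and 3118 to 3740 lower genes, and 0 called genes changed sign in any of these fits; signs were not compared for the authors' table. Leaving out each library gave 3053 to 3281 higher and 3057 to 3258 lower genes. A log2 fold change of at least 1 left 627 higher and 804 lower, by construction. The replicate block gave 3569 higher and 3522 lower genes; libraries with the same number deviated together with r of 0.045, 0.044 and -0.044, and not every library correlated best with its own number. Lists past the test numbered 9, with 8 to 10 in most alternatives, 6 with the length and GC trend or both trends removed, 0 with an estimated correlation (lowest adjusted p 0.54) and 27 with fry, which tests selected genes against no change. Without control 1, CSF1R lost its call, and IL3RA lost it without control 2 or without knockout 2.

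Removing the trend of neighbouring genes shifted the log2 fold changes of all genes by a median of -0.18. It left 2257 higher and 2469 lower genes, and removing both trends left 2292 and 2514. The first turned the sign of 1264 called genes and the latter of 1274. Local medians lay away from 0 even where directions were mixed, as genes with little change are mostly outside the table. On chromosome 1, 42.9% of genes between 180 and 190 Mb were higher, with a median of -0.38. Between 20 and 30 Mb 56.9% were higher, with a median of 0.26. This removal can therefore shift genes too far, so turned signs and lost or gained calls may partly reflect the selection. With the neighbouring trend removed, log2 values turned for BRCA1 (0.000608), SPG7 (-0.033), CLEC2B (-0.34), RPL27 (0.10) and the t(8;21) list median (-0.34). With both removed, they turned for BRCA1 (0.24), CLEC2B (-0.23), CD3D (-0.058), SDF2L1 (-0.10), RPL8 (-0.10) and the medians of the t(8;21) (-0.24), ER stress (-0.011) and cytosolic ribosomal (-0.016) lists. Of the list and gene results, 8 lost their call with the length and GC trend removed, 23 with the neighbouring trend removed and 29 with both removed, beside those that turned. With the neighbouring trend removed these include the mitochondrial ribosome and antioxidant lists, SDHA, MGME1, HOXA10, CEBPA, RUNX1 and RPL12. With both removed they include the complex I, mtDNA, mitochondrial ribosome and antioxidant lists, NDUFS6, ATP5PF, MT-ND1, CCNE1, BRIP1 and CALCOCO2, and the TCA list at a median of 0.35 against 0.31 before. The cause was not tested for single genes. With 3 libraries a group, small changes of low genes may be missed, though recovery was not tested by level or depth. In addition, 4 lists had too few tested members for a list test.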

Other observations

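The tests of gene classes, of chance placement, of segment copies, of both trends together and of library splits were chosen after the results were seen. Transcription factor genes of the C2H2 zinc finger family, as the table's own annotation names them, were mostly lower. The class was 1 of 9 classes of factor or biotype that were looked at. Of 220 tested genes 165 were called lower and 39 called higher, with a median log2 fold change of -0.48. By sign alone, 20% were above 0, against 51.3% of the other genes (Fisher's exact test of direction, two-sided, adjusted p = 4.81e-20 over the 9 classes). On chromosome 19, 47 of 68 C2H2 genes were called lower and 15 called higher. Of the other 441 genes there 312 were called higher and 105 called lower. With both trends removed the median of the class was -0.34. Among noncoding RNAs, 105 of 172 lincRNA genes were called lower and 57 called higher, with a median of -0.76. By sign alone, 35.5% were above 0, against 50.7% of the other genes (Fisher's exact test, adjusted p = 0.00023). Of 163 antisense genes 92 were called lower and 62 called higher, with a median of -0.62. By sign alone, 39.9% were above 0, against 50.6% (Fisher's exact test, adjusted p = 0.016). Fisher's test treats genes as independent, but neighbouring genes moved together, so the p-values of these classes may be too small. With the trend of neighbouring genes removed the lincRNA and antisense medians were -0.69 and -0.35, and with both trends removed -0.73 and -0.54. Genes with little change are mostly outside the table, so the size of the class medians partly reflects that selection. Antisense counts are uncertain where strand was not used.

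Single genes of antigen presentation, picked after their values were seen, went both ways, and no test of a split was run. HLA-C and B2M of class I had log2 fold changes of 1.02 and 1.20, and NLRC5, the class I transactivator, 0.91. On the class II side, HLA-DRA and HLA-DPB1 were at -5.86 and -3.02, CIITA at -1.84 and HLA-DPA1 at -0.60, where the last missed the threshold (adjusted p = 0.066). HLA-DMB, at 2.57, and CD74, at 1.22, were higher, so the class II genes named here did not all move the same way. Low granulocytic genes also rose: LYZ went from 2.30 to 38.2 and ELANE from 8.24 to 35.7, with log2 fold changes of 3.81 and 2.03.

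Neighbouring genes moved the same way more often than by chance. Of 6751 pairs of adjacent genes 63.1% shared a direction, against at most 51.7% in 1000 permutations of the directions over the genome. The share was 62.6% after the length and GC trend was removed, against at most 51.9% in permutations, which argues against that trend as the source. A candidate explanation is that the 2 cell populations carry different numbers of copies of some chromosome segments. In the 20 segments where genes outside the lists were mostly lower, 74.2% of 62 list members were lower, counted by sign alone. Of list members elsewhere, 28.6% were lower (Fisher's exact test, two-sided, p = 7.17e-12). The share was just under the 75% written as its threshold. Any cause that moves neighbouring genes together gives such a share, so it cannot tell segment copies from another regional cause. Segment copies therefore stay open as an explanation.

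The rise of the nuclear respiratory chain genes was set against the same trends. The median of the 60 subunit genes was 0.53, and 0.42 after the length and GC trend was removed, above the 0.29 at the upper end of the 95% range of 10000 random lists matched on mean level. It was 0.32 after the trend of neighbouring genes was removed, with a bound of 0.14. Neither trend alone accounts for the rise. With both removed it was 0.19, with a bound of 0.17, at percentile 98.6, so a joint contribution of the trends to most of the rise cannot be told apart from an effect of SETD8 loss, because little of the median is left above the random lists.

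The fall of the integrated stress response genes did not follow either trend. The median of -0.65 was -0.67 after the length and GC trend was removed and -0.81 after the trend of neighbouring genes was removed, below the -0.26 and -0.20 at the lower end of the 95% range of matched random lists. What lies behind the fall is open, and the design does not separate SETD8 loss from other differences between the 2 cell populations. For the count of called genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 7070, and the highest of the others gave 0. The genes were selected on the real split, and 10 splits are too few for a share under 0.05.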
